A study of Mus musculus with 5 samples.

How the data were processed

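Lenses of embryonic day 14 mice were profiled by RNA sequencing in 3 control and 2 N-myc knockout libraries. Per the labels' protocols, lenses of single animals were lysed in TRIzol and stored frozen, lysates were pooled before column purification of the RNA, and samples with traces of genomic DNA were treated with DNase I. The number of animals in a pool, the sequencing read type and the strand setting are not given in the sources used here. The authors deposited 1 table of raw counts per gene symbol, and the unit was checked on the values, which are whole numbers with a different total in each library. Trim Galore 0.3.7, TopHat2 2.0.13, HTSeq 0.6.1, Cufflinks 2.2.1, DESeq2 and the genome build mm10 are named per the submitters' processing notes, with no role or order. The annotation and the rule by which 12370 symbols were kept are not given in the sources used here. Of these symbols, 61 had 0 counts in all libraries. Reads of genes that overlap or lie antisense to each other cannot be told apart without a stated strand setting, and near-identical copies (gamma-crystallins, histones, ribosomal protein pseudogenes) can share or lose reads, so single members of such families are uncertain.

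Groups were taken from the sample titles. The totals were 13162384, 13663255 and 13211451 counts in control replicates 1 to 3 and 13214989 and 13746416 in knockout replicates 1 and 2. In a self-test, counts were simulated for the 12035 genes tested in this comparison with 200 genes changed, 5 times. edgeR recovered 34.0% of the 1.5-fold and 70.8% of the 2-fold changes, with a mean of 12.6 false calls. The test camera called a planted list of 50 genes changed 1.3-fold in 5 of 5 simulations. Genes were simulated as independent of each other, and libraries of a group differed only by random spread. The self-test therefore does not cover lists of genes that vary together or a library that stands apart. The libraries of a group were compared pairwise by a chi-square test over genes with at least 10 counts. Chi-square over its degrees of freedom was between 9.98 and 23.39, so no pair agreed within sampling noise, and each library was counted as 1 sample. P-values measure the spread between these pools.

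Counts were analysed in R 4.3.3 with edgeR 4.0.16 as the main test. Genes were kept with filterByExpr by group (minimum count 10), which removed 335 symbols. Libraries were scaled by TMM, dispersions were estimated with estimateDisp (biological coefficient of variation 14.1%), and the groups were compared with glmQLFit and glmQLFTest with package defaults and no covariate. P-values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. CPM values use TMM-scaled totals and are given as mean ± SD over 3 control and 2 knockout libraries, and folds are the fitted edgeR folds. The SE of a log2 fold change was the fold change divided by the square root of the F statistic.

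Before the data were examined, 38 gene lists from textbook knowledge were fixed, together with the design, the processing alternatives and the rule for named genes. The lists covered crystallins, fibre membrane and cytoskeleton, organelle and nuclear removal, lens transcription factors and epithelium, the MYC family, ribosome biogenesis, ribosomal proteins, MYC target metabolism, tRNA synthetases, stress responses, the cell cycle, cell death, signalling pathways, the lens capsule, energy and sterol metabolism, lysosomes, RNA quality, other cell types and sex-linked transcripts. Some genes belong to more than 1 list. A total of 37 lists with at least 5 tested members were tested with camera in limma 3.58.1, at a preset inter-gene correlation of 0.01 and with an estimated one, and with fry. With the preset correlation 21 lists were called, 11 lower and 10 higher. With an estimated correlation 0 lists were called by camera (lowest adjusted p = 0.42), and fry's directional test called 0 (lowest adjusted p = 0.053). Fry's test for changes in either direction gave adjusted p from 4.4e-05 (red blood cells) to 0.59 (sex-linked transcripts). Some lists that camera did not call therefore passed it. The estimated correlations ran from -0.06 (MYC family) to 0.97 (skeletal muscle). Values of lists per library are means of log2 (CPM + 1). Named genes were Mycn, Myc, Mycl and Dnase2b, the 10 largest rises and falls among called genes with a mean CPM of at least 5, no overlap of the groups' ranges and no predicted-gene name, up to 4 called members of each list by smallest adjusted p (2 members as values where none was called), and the 5 genes with the highest mean CPM.

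Gene positions came from GENCODE vM21 (GRCm38, the build mm10), by symbol, for 97.9% of the tested genes. Transcript length and GC content were those of the longest transcript of a symbol in the same release, known for 98.1% of tested genes and for 64 of 64 ribosomal protein genes. Each library's trend on these was fitted by loess to log2 CPM and entered as an offset in an alternative. This alternative and edgeR's newer quasi-likelihood method were chosen after seeing the data. The alternatives fixed before were DESeq2 1.42.0, limma-voom, edgeR's earlier quasi-likelihood method, camera with an estimated correlation, RLE, upper-quartile and library-total scaling, scaling without crystallins, no filter, a filter of at least 50 counts in 2 libraries, the replicate number as a block, a test against a 1.2-fold change, an adjusted p under 0.1 and leaving out each library.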

Results

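RNA from embryonic day 14 mouse lenses was sequenced in 5 libraries. The 3 control libraries came from Cre-negative embryos with loxP-flanked alleles of N-myc. The 2 knockout libraries came from embryos that carried the same alleles and Mlr10-Cre, a transgene that expresses the Cre recombinase in the lens. Control genotypes with and without loxP-flanked c-myc are both described in the labels, and which of them each control library had is not given in the sources used here. The series calls the libraries of a group biological replicates, and lenses of single animals were pooled before RNA extraction. The gene counts of a library summed to between 13162384 and 13746416 over 12370 gene symbols.

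The comparison asked which transcripts differ in the lens when N-myc is deleted there. Both knockout libraries and no control library carried Mlr10-Cre. For every result below, effects of the transgene therefore cannot be told apart from those of the deletion. Mycn, the gene for the transcription factor N-myc (chromosome 12, 12936093 to 12941914, GRCm38), was 2.16-fold lower in the knockout lenses. It stood at 69.6 ± 17.3 CPM (counts scaled for library size; SD, n = 2) against 150.2 ± 11.0 CPM in the controls (SD, n = 3), with a log2 fold change of -1.11 (SE 0.15, edgeR quasi-likelihood adjusted p = 0.0097). The raw Mycn counts were 2066, 1955 and 1848 in the controls and 801 and 1141 in the knockouts, so both knockout libraries lay below each control library. The position of the loxP sites is not given in the sources used here, and the count covers the whole gene, exons outside the deleted part included. Without control replicate 2 the Mycn log2 fold change was -1.11 with an adjusted p of 0.056, the highest of its 18 alternatives (lowest 1.2e-10).

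Of the other MYC genes, Myc had a log2 fold change of 0.63 (SE 0.21, edgeR adjusted p = 0.073) and Mycl one of 0.21 (SE 0.13, edgeR adjusted p = 0.28), and neither passed the test. Myc did pass with DESeq2 (adjusted p = 0.033), with library totals as the only scaling (0.046) and without control replicate 1 (0.019), within a range of 0.019 to 0.21 over its 18 alternatives. Of the 12 tested genes for MYC proteins and their partners, 3 fell, over all genes tested and adjusted over the list alone. They were Mycn, Max, the common dimerization partner of the family (1.32-fold lower, log2 -0.40, SE 0.092), and Mxd1, which competes for Max (1.43-fold lower, log2 -0.51, SE 0.12). The list as a set did not pass camera's test (adjusted p = 0.3), and its mean log2 fold change of -0.07 had the opposite sign to its median of 0.06. From this list 0 genes passed without control replicate 2, and 1 without control replicate 3 or knockout replicate 1.

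Of 12035 genes tested, 960 were higher and 1024 lower in the knockout lenses, which is 16.5% of the tested genes (edgeR adjusted p under 0.05). The median fold was 1.57 among the higher and 1.43 among the lower genes, and 264 rose and 78 fell by 2-fold or more. The largest falls after the rule for named genes were those of Tmprss11e, a transmembrane serine protease (14.2-fold, 16.4 ± 7.49 to 1.15 ± 0.813 CPM), Nlrc5, an activator of MHC class I genes (10.5-fold, 37.4 ± 5.95 to 3.55 ± 0.462 CPM), and Dnase2b (7.97-fold). Birc7, Stx11, Lrrtm2, Poln, Scn11a, Rnf180 and Lctl followed, 3.52-fold to 6.13-fold lower. The largest rise was that of Mt1, a metallothionein, from 0.331 ± 0.155 to 96.1 ± 1.73 CPM (log2 fold change 8.14, SE 0.19, edgeR adjusted p = 9.7e-07). Its raw counts were 2, 5 and 6 in the controls and 1325 and 1356 in the knockouts. Lrrn1 (7.88-fold), Aldh1a3 (7.93-fold), Mab21l2 (7.47-fold) and Col2a1, the type II collagen chain (6.47-fold), also rose. Nfix, Col14a1, Dlk1, Alx4 and Lum completed the 10 largest rises, but rested on knockout replicate 1. Dlk1, for example, was at 110.4 CPM there and at 6.96 CPM in knockout replicate 2, against 6.34 ± 0.439 CPM in the controls. Without knockout replicate 1 the edgeR adjusted p of these 5 genes lay between 0.26 and 0.79, and of the 5 only Lum passed with the length and GC trends removed.

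Calls depended on single libraries. The numbers of higher and lower genes were 21 and 17 without control replicate 2, 132 and 105 without control replicate 3, and 179 and 113 without knockout replicate 1. In the fit without control replicate 2, 3157 genes still had an unadjusted p under 0.05, against 4311 with all libraries. Of the 123 named genes that passed the test, 10 did so in each of the 18 alternatives, namely Dnase2b, Nlrc5, Lrrtm2, Scn11a, Mt1, Lrrn1, Col2a1, Ndrg1, Hist1h3f and Ermap. The split was 1511 higher and 637 lower (70.3% higher, against 48.4%) when libraries were scaled by their totals only. The knockout libraries also stood apart from each other. On principal component 1, with 62.3% of the variance, the controls lay between -21.4 and -19.7, knockout replicate 1 at 50.3 and knockout replicate 2 at 11.9. For 52.5% of the tested genes the ranges of the groups did not overlap, where chance gives 20% for a single gene. Genes vary together, so the share over all genes can lie far from 20% without a group effect.

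Fold changes followed the GC content of the transcripts. Among the 2361 tested genes with the lowest GC content (31% to 43.9%), 37 were higher and 495 lower, and among the 2361 with the highest (55.5% to 78.9%), 426 were higher and 47 lower. The median log2 fold changes of these groups were -0.24 and 0.26. Across genes, which are not independent replicates, Spearman's rho between log2 fold change and GC content was 0.46. With each library's trend on transcript length and GC content removed, 567 genes were higher and 721 lower, and 990 of the 1984 calls remained. Of the 1984 called genes, 13 then had a fold change of the opposite sign.

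**Figure D1:**
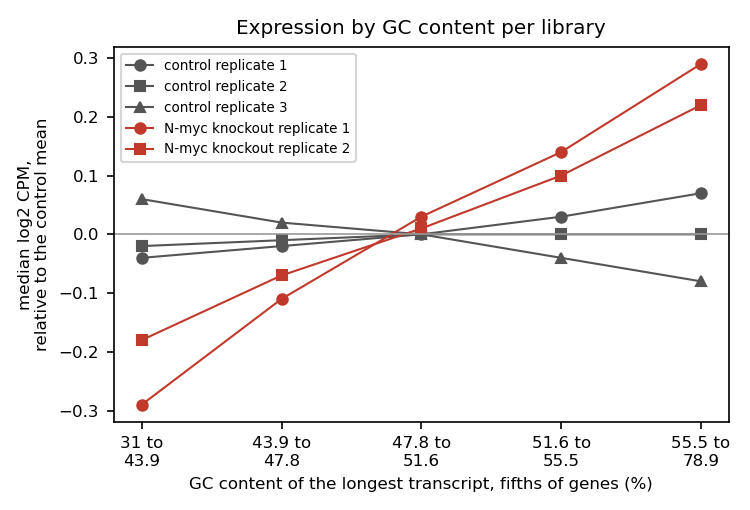
Median log2 CPM relative to the control mean (vertical axis) in each library for tested genes in 5 groups of rising GC content of their longest transcript (horizontal axis). Knockout replicates 1 and 2 run from -0.29 and -0.18 in the lowest group to 0.29 and 0.22 in the highest, while the controls stay between -0.08 and 0.07.

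Dnase2b, the nuclease that degrades DNA when fibre cells lose their nuclei, went from 41.7 ± 11.1 CPM in the controls (SD, n = 3) to 5.23 ± 0.313 CPM in the knockouts (SD, n = 2; log2 fold change -2.99, SE 0.25, edgeR adjusted p = 0.0024). Of 22 genes for fibre membrane and cytoskeleton proteins, 9 fell and the other 13 did not pass the test, and 10 fell when adjusted over the list alone. Bfsp1, the beaded filament protein filensin, fell 3.07-fold from 1729 ± 384 to 564 ± 134 CPM. Caprin2, an RNA-binding protein, fell 2.25-fold, Lenep 2.06-fold and Tmod1, which caps actin filaments, 1.97-fold. The list had a mean log2 fold change of -0.56 (camera adjusted p = 1.1e-06), with an adjusted p = 0.42 with an estimated correlation.

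Of the 16 crystallin genes, 5 fell (6 adjusted over the list alone). Crygf was 3.06-fold lower, Crygd 2.25-fold, Crygb 2.12-fold and Cryab, the small heat shock protein alpha-B crystallin, 1.57-fold. The gamma-crystallin genes are near-identical copies of each other, so counts of single members are uncertain. The most expressed crystallins did not pass the test. Cryaa stood at 45827 ± 5317 CPM in the controls and 47204 ± 4178 in the knockouts, Crybb1 at 13604 ± 1319 and 14342 ± 1141, and Cryba1 had a log2 fold change of -0.51 (SE 0.20, edgeR adjusted p = 0.11). The crystallin list had a mean log2 fold change of -0.54 (camera adjusted p = 0.00017), with an adjusted p = 0.56 with an estimated correlation. The mean was -0.35 without knockout replicate 1. Per library the list was at -0.74 and -0.33 in knockout replicates 1 and 2. The controls ranged from -0.31 to 0.28, so knockout replicate 2 lay close to the lowest control. Crystallins made up 10.3% to 14.1% of a library's counts.

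**Figure D2:**
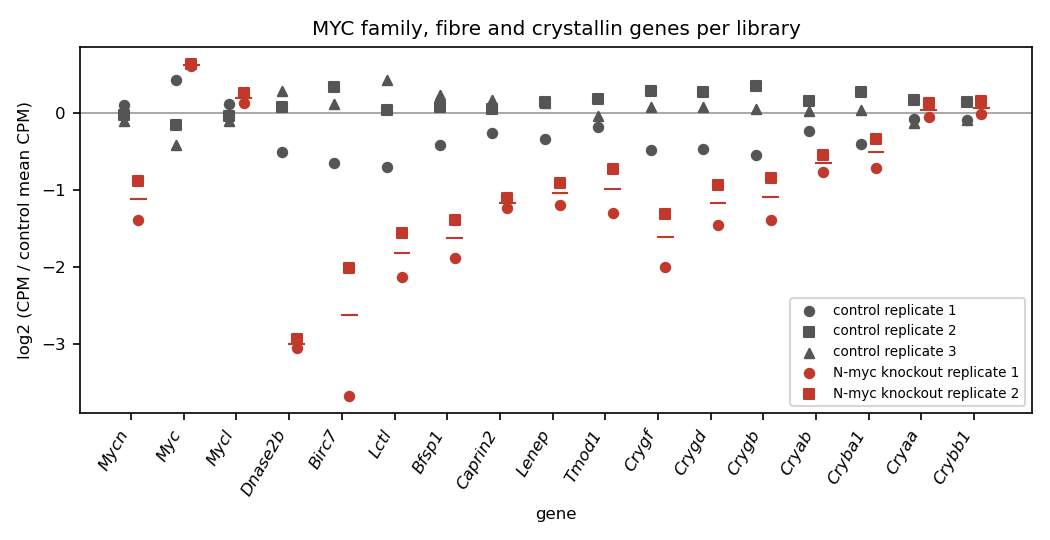
Log2 ratio of each library's CPM to the control mean CPM (vertical axis) for MYC family, fibre and crystallin genes (horizontal axis). Grey symbols are the 3 control libraries, red symbols the 2 knockout libraries and red lines the ratio of the knockout mean. Mycn (log2 fold change -1.11) and Dnase2b (-2.99) lie below the controls in both knockout libraries, and Cryaa (0.04) does not.

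Of 26 genes tied to the removal of organelles and nuclei, 7 fell and 2 rose (8 and 3 adjusted over the list alone). Besides Dnase2b, Bnip3l, a mitophagy receptor, fell 1.39-fold, while Tbc1d20, a Rab GTPase-activating protein, rose 1.43-fold. The list's mean log2 fold change was -0.23 (camera adjusted p = 0.017), with an adjusted p = 0.48 with an estimated correlation. Without knockout replicate 2 its adjusted p was 0.094, and over the list's alternatives it ran from 0.0009 to 0.48. With control replicate 2 left out, 0 crystallin, 0 fibre and 1 organelle gene passed edgeR's threshold. The numbers were 0, 3 and 2 lower without control replicate 3, and 1, 3 and 2 without knockout replicate 1, while 8 crystallin genes fell without control replicate 1 or knockout replicate 2.

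Of 30 lens transcription factor genes, 7 rose and 3 fell (8 and 3 adjusted over the list alone). Ell2, a transcription elongation factor, fell 1.60-fold, and Tfap2b, an AP-2 factor, rose 3.20-fold from 8.57 ± 3.11 to 27.5 ± 5.17 CPM. Tfap2b was at 31.1 and 23.8 CPM in knockout replicates 1 and 2. Mab21l2 rose to 10.7 and 41.6 CPM in the knockout libraries from a mean of 3.49 CPM, and Meis1 rose 1.36-fold. The retina genes were also higher in knockout replicate 2 than in replicate 1 (means of 1.42 and 0.60 on the log2 scale). The rise of Mab21l2 therefore cannot be assigned to lens cells. The list did not pass camera's test (mean log2 fold change 0.22, adjusted p = 0.25), but did without knockout replicate 1 (0.28, adjusted p = 0.0046, range over its alternatives 0.0046 to 0.79). Among 22 lens epithelium genes, 2 rose, over all genes tested and adjusted over the list alone: Mab21l2 and Ptn, a secreted growth factor (2.07-fold). That list's mean log2 fold change was 0.23 (camera adjusted p = 0.16, and 0.023 without knockout replicate 1, range 0.023 to 0.44). In the fit without control replicate 2, 0 genes of both lists passed edgeR's threshold. Without control replicate 3, 1 transcription factor gene rose and 1 fell, and 4 rose and 1 fell without knockout replicate 1.

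Of 64 genes for cytosolic ribosomal proteins, 27 fell and 37 did not pass the test (36 fell adjusted over the list alone), and 62 of the 64 had a fold change below 0 on the log2 scale. Rpl4 fell 1.58-fold from 752 ± 83.2 to 476 ± 43.6 CPM, Rpl5 1.66-fold, Rpl15 1.73-fold and Rpl39 2.60-fold. Ribosomal protein genes have many processed pseudogenes, so counts of single members are uncertain. The mean log2 fold change was -0.50 (camera adjusted p = 4.9e-13), with an adjusted p = 0.44 with an estimated correlation, and the controls ranged from -0.15 to 0.16 against -0.63 and -0.31 in the knockout libraries. Of 52 ribosome biogenesis genes, 18 fell (25 adjusted over the list alone), among them the nucleolar genes Npm1 (1.87-fold), Gnl3 (1.75-fold), Ncl (1.65-fold) and Wdr43 (1.47-fold). Of 22 aminoacyl-tRNA synthetase genes, 15 fell (18 adjusted over the list alone), with Iars 1.63-fold, Gars 1.58-fold, Eprs 1.47-fold and Tars 1.45-fold lower. Of 44 textbook MYC target genes of metabolism and growth, 20 fell and 1 rose (25 and 1 adjusted over the list alone). Tfrc, the transferrin receptor, fell 1.64-fold, Hspd1, a mitochondrial chaperonin, 1.66-fold, Eif2s1, a subunit of translation initiation factor 2, 1.64-fold and Paics, an enzyme of purine synthesis, 1.61-fold. The mean log2 fold changes of these 3 lists were -0.31, -0.40 and -0.30 (camera adjusted p = 1.5e-08, 3.2e-10 and 5.8e-08), each with an adjusted p = 0.42 with an estimated correlation. Without control replicate 2, edgeR called 0 genes of these 4 lists, and without control replicate 3 or knockout replicate 1 between 1 and 3 of each. With the length and GC trends removed, 24, 19, 13 and 21 genes of the ribosomal protein, ribosome biogenesis, synthetase and MYC target lists fell.

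Genes of DNA replication and mitosis did not pass the test. None of the 40 DNA replication genes did with edgeR, DESeq2 or limma-voom, nor when adjusted over the list alone, with 7 at an unadjusted edgeR p under 0.05. The mean log2 fold change was 0.07 (camera adjusted p = 0.3), Mcm5 having 0.29 (SE 0.083, edgeR adjusted p = 0.05007) and Pole 0.25 (SE 0.080). Fry's test for changes in either direction gave this list an adjusted p of 0.013, against 0.072 for the mitosis list. Mcm5 passed in 4 of its 18 alternatives (adjusted p from 0.027 to 0.49) and Pole in 1 (0.031 to 0.67), and with library totals as the only scaling 2 DNA replication genes were called higher. Leaving out control replicate 1 gave 1 higher and leaving out knockout replicate 2 gave 1 lower. Of the 38 mitosis genes, 0 passed with the same tools or when adjusted over the list alone and 0 had an unadjusted edgeR p under 0.05, with a mean of 0.03 (camera adjusted p = 0.73), Aurka having -0.25 (SE 0.11) and Cdc20 0.22 (SE 0.10). With the length and GC trends removed the mitosis mean was 0.11 (camera adjusted p = 0.045, range over its alternatives 0.045 to 0.9). Of 18 genes for G1 cyclins and cyclin-dependent kinase inhibitors, Ccnd2, cyclin D2, fell 1.42-fold from 1412 ± 191 to 992 ± 128 CPM. Cdk2 rose 1.35-fold and Gas1, a growth arrest gene, 2.47-fold, to 63.5 and 36.9 CPM in knockout replicates 1 and 2. Adjusted over the list alone, 1 fell and 3 rose, and the list did not pass camera's test (mean 0.20, adjusted p = 0.57). Of 27 p53 target and cell death genes, Ccng1, cyclin G1, fell 1.94-fold, Aen, a nuclease, fell 1.40-fold and Bcl2l1, which encodes Bcl-xL, rose 1.26-fold, with the same counts adjusted over the list alone (mean 0.12, camera adjusted p = 0.64). From the G1 and p53 lists 0 genes passed without control replicate 2, and 0 and 1 without control replicate 3 and 1 and 1 without knockout replicate 1. Bcl2l1 had a log2 fold change of 0.18 and did not pass with the length and GC trends removed.

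Of 22 FGF pathway genes, 8 rose (11 adjusted over the list alone), including Il17rd, an FGF antagonist (3.92-fold), the ligands Fgf15 (3.90-fold) and Fgf9 (3.87-fold), and the receptor Fgfr1 (1.43-fold, 146 ± 8.37 to 208 ± 12.2 CPM). Of 21 Notch pathway genes, 6 rose (10 adjusted over the list alone), with Dll1 3.20-fold, Hes5 2.19-fold, Notch1 1.50-fold and Maml1 1.45-fold higher. Of 21 Wnt pathway genes, 8 rose (12 adjusted over the list alone), with Dkk2, an antagonist, 2.67-fold, the coreceptor Lrp5 2.22-fold, Tcf7l1 1.44-fold and Wnt7a 1.38-fold higher. Fgf15, Dll1 and Hes5 are also known from retinal progenitors, and the retina genes were higher in the same libraries by a mean of 0.60 and 1.42 on the log2 scale. Il17rd (24.7 and 12.1 CPM in knockout replicates 1 and 2) and Dkk2 (15.1 and 11.5 CPM) were higher in replicate 1. So were the mesenchyme genes (2.30 and 0.39), whereas Notch1 was about equal (184.9 and 188.2 CPM). Which cells these rises came from was not tested. The FGF, Notch and Wnt lists had mean log2 fold changes of 0.52, 0.43 and 0.48 (camera adjusted p = 4.3e-05, 6.6e-05 and 5.4e-05), each with an adjusted p = 0.42 with an estimated correlation. With the length and GC trends removed 6, 3 and 2 of their genes rose, and the Notch mean was 0.27. Maml1 (log2 fold change 0.31), Wnt7a (0.29) and Tcf7l1 (0.25) then did not pass. When control replicate 2 was left out, 0 of the genes of these 3 lists passed edgeR's threshold. Without control replicate 3, 1, 0 and 2 did, and without knockout replicate 1, 3, 2 and 2. Of 24 BMP and TGF-beta pathway genes, Bmpr1a, a BMP receptor, fell (log2 fold change -0.38, SE 0.092), 0 passed when adjusted over the list alone, and the list did not pass camera's test (mean 0.36, adjusted p = 0.18). Its mean was 0.17 without knockout replicate 1, and Bmpr1a had a log2 fold change of -0.17 and did not pass with the length and GC trends removed.

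Of 25 genes for the lens capsule and basement membranes, 7 rose and 1 fell (9 and 2 adjusted over the list alone). Lamb2, a laminin chain, rose 1.79-fold, Agrn, agrin, 1.77-fold from 91.1 ± 4.49 to 161 ± 18.5 CPM, and Col18a1 1.50-fold, while P4ha1, a collagen prolyl hydroxylase, fell 1.67-fold. The list's mean log2 fold change was 0.31 (camera adjusted p = 0.0011), with an adjusted p = 0.42 with an estimated correlation. With the length and GC trends removed 2 rose and 1 fell, the log2 fold change of Col18a1 was 0.23 and did not pass, and the mean was 0.15 (adjusted p = 0.29, range over its alternatives 0.00028 to 0.42). Without control replicate 2, 0 of its genes passed edgeR's threshold, and 3 rose without control replicate 3 or knockout replicate 1, with a mean of 0.19 in the latter. The list was at 0.39 and 0.19 in knockout replicates 1 and 2, where the genes for periocular mesenchyme were at 2.30 and 0.39.

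Of 29 genes of glycolysis and the hypoxia response, 8 fell (11 adjusted over the list alone), with Bnip3, a mitophagy receptor, 2.29-fold, Ndrg1 2.09-fold, P4ha1 1.67-fold and Kdm3a, a histone demethylase, 1.34-fold lower. Of 60 oxidative phosphorylation genes, 6 fell (0 adjusted over the list alone), with Cycs, cytochrome c, 2.01-fold, Cox5a 1.52-fold, Atp5f1 1.40-fold and Atp5b 1.39-fold lower. Of 24 cholesterol synthesis genes, 5 fell (11 adjusted over the list alone), with Idi1 2.17-fold, Insig1 1.38-fold, Hmgcs1 1.38-fold and Cyp51 1.32-fold lower. Of 20 heat shock genes, 11 fell (12 adjusted over the list alone), with Dnaja1 1.60-fold, Chordc1 1.51-fold, Hsp90aa1 1.50-fold and Hsp90ab1 1.46-fold lower (2562 ± 124 to 1749 ± 137 CPM). The mean log2 fold changes of these 4 lists were -0.33, -0.33, -0.22 and -0.27 (camera adjusted p = 3.9e-05, 4.3e-06, 0.0049 and 4.3e-06), with an adjusted p = 0.48, 0.64, 0.44 and 0.44 with an estimated correlation. From these 4 lists 1 gene passed edgeR's threshold without control replicate 2, and without control replicate 3 or knockout replicate 1 at most 2 of each. Without control replicate 1 or knockout replicate 2, 12 oxidative phosphorylation genes fell. The oxidative phosphorylation mean was -0.17 without knockout replicate 1, -0.20 without control replicate 2, -0.51 without knockout replicate 2 and -0.21 with the length and GC trends removed, and the glycolysis mean was -0.18 without control replicate 2. Per library the oxidative phosphorylation list was at -0.46 and -0.15 in knockout replicates 1 and 2. The controls ranged from -0.18 to 0.20, so knockout replicate 2 lay within them. Among the named genes, Atp5f1 (log2 fold change -0.05), Cox5a (-0.31), Cycs (-0.74), Bnip3 (-0.88), Hmgcs1 (-0.28) and Chordc1 (-0.20) did not pass with the length and GC trends removed.

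In 3 further lists members went both ways and camera's test was not passed. Of 19 amino acid stress response genes, Asns, asparagine synthetase, fell 1.82-fold, Slc7a11, a cystine transporter, 1.52-fold and Psat1 1.36-fold, and Vldlr rose 1.24-fold (4 fell and 1 rose adjusted over the list alone; list adjusted p = 0.3). Of 23 unfolded protein response genes, the folding factors Pdia6 and Canx fell 1.43-fold and 1.38-fold and Syvn1 rose 1.34-fold, with the same counts adjusted over the list alone (list adjusted p = 0.52). Of 31 lysosome genes, Grn and Psap rose 1.43-fold and 1.29-fold and Atp6v1a fell 1.22-fold, and 2 rose and 0 fell adjusted over the list alone (list adjusted p = 0.82). Without control replicate 2 or control replicate 3, 0 genes of these 3 lists passed edgeR's threshold, and 1 did without knockout replicate 1. Slc7a11 (log2 fold change -0.41), Psat1 (-0.38), Canx (-0.26), Syvn1 (0.20) and Atp6v1a (-0.16) did not pass with the length and GC trends removed.

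Of 21 genes for periocular mesenchyme and pericytes, 8 rose (15 higher and 1 lower adjusted over the list alone), among them Eya2 (4.44-fold), Cspg4 (1.97-fold) and Pdgfrb (1.75-fold). The list was higher by 2.30 in knockout replicate 1 and by 0.39 in knockout replicate 2 on the log2 scale, and lay between -0.47 and 0.57 in the controls. Its mean log2 fold change was 1.85 (camera adjusted p = 7e-06), with an adjusted p = 0.47 with an estimated correlation. Without knockout replicate 1, 0 of its genes passed edgeR's threshold and the mean was 0.27, and Cspg4 had a log2 fold change of 0.61 and did not pass with the length and GC trends removed. Of 21 genes for retina and neurons, 14 rose (17 adjusted over the list alone), among them the retinal progenitor genes Atoh7 (6.66-fold) and Rax (5.15-fold), and the neurofilament gene Nefl (3.04-fold). That list was higher by 0.60 in knockout replicate 1 and by 1.42 in knockout replicate 2, with a mean log2 fold change of 1.37 (camera adjusted p = 1.4e-08) and an adjusted p = 0.44 with an estimated correlation. With control replicate 2 left out, 0 genes of both lists passed, and without control replicate 3, 1 of each. The mesenchyme and retina genes that rose numbered 4 and 8 without control replicate 1, and 16 and 7 without knockout replicate 2, where the retina mean was 0.77.

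**Figure D3:**
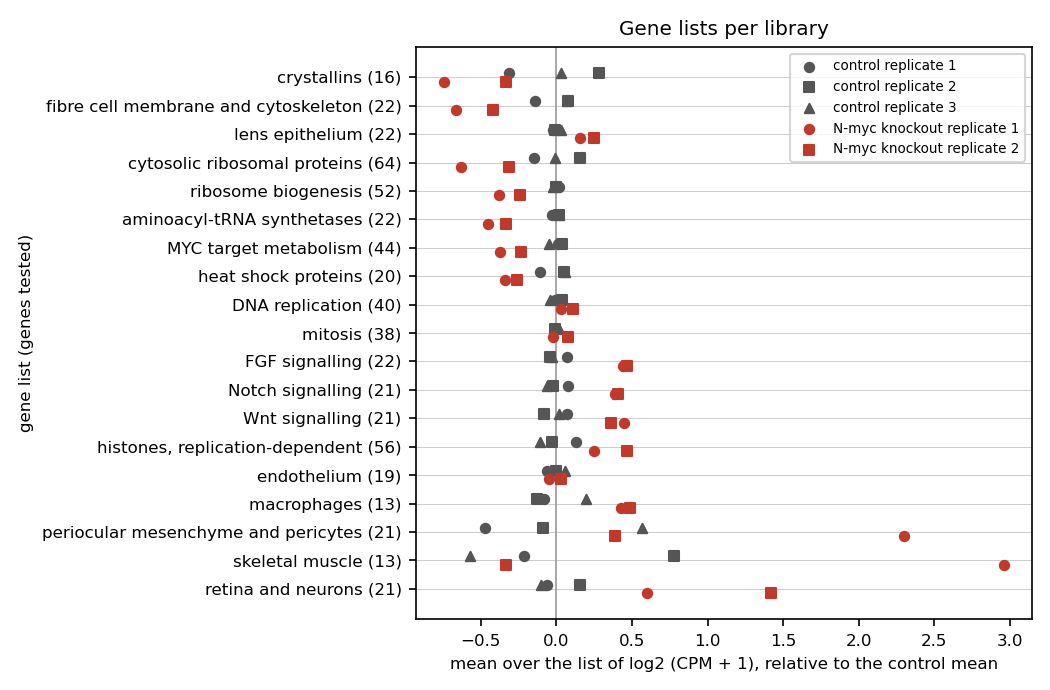
Mean over each gene list of log2 (CPM + 1) relative to the control mean (horizontal axis) in each library, with the number of genes tested beside each list (vertical axis). Grey symbols are the 3 control libraries and red symbols the 2 knockout libraries. The muscle list is at 2.96 in knockout replicate 1 and at -0.33 in knockout replicate 2, whereas the mitosis list is at -0.02 and 0.08.

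None of 13 skeletal muscle genes passed the test with edgeR (8 at an unadjusted p under 0.05; 1 with DESeq2 and 0 with limma-voom), also when adjusted over the list alone. Their mean log2 fold change was 2.38 (camera adjusted p = 0.0086), with an adjusted p = 0.67 with an estimated correlation, and it was -0.81 without knockout replicate 1 and 2.14 without control replicate 1 (adjusted p = 0.072, range over its alternatives 7.8e-18 to 0.67). Without knockout replicate 2 it was 3.35, with 16 of the 16 muscle genes then tested called higher. Myh8, a perinatal myosin, was at 63.9 CPM in knockout replicate 1 and 3.01 CPM in knockout replicate 2 against 3.28 ± 3.88 CPM in the controls, and Des, desmin, at 16.8 and 1.58 against 1.86 ± 0.720. Of 13 macrophage genes, Cd68 rose 1.85-fold and each of the 13 had a fold change above 0 on the log2 scale (mean 0.59, camera adjusted p = 0.014), with an adjusted p = 0.44 with an estimated correlation. Adjusted over the list alone 1 rose, and the list's adjusted p was 0.056 without control replicate 1 and 0.13 without knockout replicate 2 (range over its alternatives 0.0012 to 0.44). Of 19 endothelial genes, Flt1, a VEGF receptor, fell 1.27-fold, 0 passed when adjusted over the list alone, and the list mean was -0.03 (camera adjusted p = 0.9). Of 8 red blood cell genes, Ermap, an erythroid membrane protein gene, fell 3.42-fold from 59.8 ± 5.87 to 17.5 ± 0.941 CPM, also when adjusted over the list alone (list mean -0.15, camera adjusted p = 0.11). Of 5 pigment cell genes, Mitf fell 1.54-fold and Pmel rose 3.21-fold, also when adjusted over the list alone (list mean 0.38 and median 0.00, camera adjusted p = 0.89). The pigment list mean was 0.61 without knockout replicate 1 and 0.05 without knockout replicate 2. None of 7 surface ectoderm genes passed with edgeR, also when adjusted over the list alone, 1 having an unadjusted p under 0.05 and 0 and 1 being called by DESeq2 and limma-voom. The list mean was 0.68 (camera adjusted p = 0.3), 1.16 without knockout replicate 2 (adjusted p = 0.029) and -0.37 without knockout replicate 1 (adjusted p = 0.51), the adjusted p ranging from 0.029 to 0.77 over its alternatives. Krt18 had a log2 fold change of 1.61 (SE 0.48, edgeR adjusted p = 0.054) and Dsp 0.85 (SE 0.60), the latter -0.93 without knockout replicate 1. None of 5 sex-linked transcripts passed with edgeR, DESeq2 or limma-voom or when adjusted over the list alone, and 0 had an unadjusted p under 0.05 (list mean -0.70, camera adjusted p = 0.52, and 0.049 without control replicate 1, range 0.049 to 0.91). Xist counts were 32011, 12684 and 64 in the controls and 7455 and 28483 in the knockouts, and the Y-linked Ddx3y was at 8.15, 49.7 and 76.7 CPM and at 31.5 and 12.6 CPM in the same order, so the share of each sex differed between libraries. Eif2s3y, also Y-linked, had a log2 fold change of -1.07 (SE 0.71, edgeR adjusted p = 0.31). The mean of the sex-linked list was -1.35 without knockout replicate 1 and -0.33 without control replicate 3. Xist and the Y-linked genes of this list go opposite ways with the share of each sex. Its mean and camera's p therefore decide nothing.

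Of the lists chosen for RNA quality, 8 of 56 replication-dependent histone genes rose (14 adjusted over the list alone), among them Hist1h3f 1.85-fold, Hist2h3b 1.66-fold, Hist1h3i 1.57-fold and Hist1h3g 1.55-fold. Their mean log2 fold change was 0.37 (camera adjusted p = 1.1e-07), with an adjusted p = 0.44 with an estimated correlation, and lay at 0.25 and 0.47 in the knockout libraries and between -0.11 and 0.13 in the controls. Histone genes are close copies of each other, so single counts are uncertain. The number that rose was 1 without control replicate 2 or control replicate 3, 5 without knockout replicate 1 and 17 without control replicate 1. Hist2h3b (log2 fold change 0.48) and Hist1h3i (0.41) did not pass with the length and GC trends removed. Of 19 immediate early genes, Fos rose 2.00-fold, Egr1 1.73-fold and Jund 1.63-fold, also when adjusted over the list alone (mean 0.35, camera adjusted p = 0.015), with an adjusted p = 0.42 with an estimated correlation. With the length and GC trends removed the mean was 0.22 (adjusted p = 0.11, range over its alternatives 0.0079 to 0.42), Egr1 (log2 fold change 0.53) and Fos (0.99) did not pass, and 0 of these genes passed without control replicate 2 or knockout replicate 1 and 1 without control replicate 3. The table held 0 mitochondrially encoded genes. Among the 5 most expressed genes, Malat1, a nuclear long noncoding RNA, fell 1.46-fold from 73065 ± 3882 to 50030 ± 6197 CPM (edgeR adjusted p = 0.019), with an adjusted p of 0.21 by edgeR's newer quasi-likelihood method and between 0.07 and 0.17 without control replicate 2, control replicate 3 or knockout replicate 1 (range over its alternatives 1.7e-06 to 0.21). Rn45s, the ribosomal RNA precursor, had a log2 fold change of 0.26 (SE 0.20, edgeR adjusted p = 0.38).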

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

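The length and GC correction and edgeR's newer quasi-likelihood method were chosen after seeing the data. Genes higher and lower in the N-myc knockout numbered 1511 and 637 with library totals only, 473 and 522 with the replicate block, 183 and 143 against a 1.2-fold change and 1812 and 1724 at an adjusted p under 0.1. With the length and GC trends removed 567 were higher. edgeR's earlier quasi-likelihood method is the package default and moved nothing. Library totals only gave list means of 0.02 (MYC family), 0.05 (unfolded protein response) and 0.05 (endothelium), and at least 50 counts in 2 libraries gave 0 (endothelium) and -0.23 (red blood cells, a call gained at adjusted p = 0.04). With limma-voom the organelle list was at -0.23 (adjusted p = 0.1). The block gave Cryaa -0.02, endothelium 0.01, lens epithelium 0.24 (adjusted p = 0.046, a call gained) and skeletal muscle 1.29 (adjusted p = 0.15, a call lost, as with limma-voom at 1.56). Libraries with the same number had correlations of deviations from their group means of -0.09 and 0.01. The deviations of 2 knockout libraries mirror each other, so this check cannot tell whether the numbers pair libraries. The length and GC correction gave Cryaa -0.02, Crybb1 -0.09, mitosis 0.11 and unfolded protein response 0.01. With an estimated inter-gene correlation the calls of crystallins (-0.54), fibre genes (-0.56), organelle removal (-0.23), ribosome biogenesis (-0.31), ribosomal proteins (-0.50) and MYC target metabolism (-0.30) were lost. Leaving out 1 library gave 21 to 1426 genes higher, 17 to 1291 lower, and log2 fold changes of -1.39 to -0.87 (Mycn), -0.05 to 0.15 (Cryaa), -0.01 to 0.17 (Crybb1), -0.93 to 1.62 (Dsp), -0.13 to 5.01 (Myh8) and -0.24 to 3.17 (Des). List means ranged over -0.27 to -0.18 (organelle removal), 0.17 to 0.26 (lens epithelium), -0.22 to 0.01 (amino acid stress), -0.03 to 0.08 (mitosis), -0.10 to 0.02 (endothelium), -0.37 to 1.16 (surface ectoderm) and -0.81 to 3.35 (skeletal muscle). A knockout arm of 1 library assumes that it varies like the controls. The cause was not tested.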

Other observations

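The gene families below were chosen only after the values were seen, as were the tests of outside tissue, of a graded response, of dilution, of the Cre transgene and of the chromosome region. Counts of the families are not given without single control libraries. Over all genes, 21 were higher and 17 lower without control replicate 2, and 132 and 105 without control replicate 3. The family counts are therefore less secure than they look.

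Each of the 8 genes for subunits of CCT, the chaperonin that folds actin and tubulin, fell, Cct2 1.66-fold and Cct5 1.64-fold (mean log2 fold change -0.65, camera adjusted p = 1.8e-10), with an adjusted p = 0.22 with an estimated correlation. Of 61 genes for translation initiation and elongation factors 29 fell and 1 rose (mean -0.32), among them Eif1a (1.88-fold lower), Eef1a1 (1.55-fold) and Eif3e (1.53-fold). Of 36 proteasome subunit genes 11 fell (mean -0.32), and of 14 host genes of small nucleolar RNAs 3 fell (mean -0.42), with Snhg14 2.85-fold and Snhg12 1.58-fold lower. Without knockout replicate 1 the CCT, translation factor, proteasome and host gene families had 3, 4, 1 and 1 genes lower and means of -0.54, -0.29, -0.21 and -0.33. Without knockout replicate 2, 17 proteasome genes were lower and the host gene mean was -0.89, and after removal of the length and GC trends 6 proteasome genes were lower and the host gene mean was -0.24. Also lower were 8 of 76 mitochondrial ribosomal protein genes (mean -0.29), 4 of 20 Hnrnp genes (-0.21) and 5 of 10 SR splicing factor genes (-0.26), but 0 of these 3 families without knockout replicate 1, where the Hnrnp mean was -0.13. After removal of the length and GC trends 7 mitochondrial ribosomal protein, 1 Hnrnp and 1 SR gene were lower and 1 Hnrnp gene higher, and the means were -0.21, -0.10 and -0.09. With library totals as the only scaling 3 mitochondrial ribosomal protein, 1 Hnrnp, 3 SR and 4 proteasome genes were lower and 1 SR gene higher. Of 39 genes for NADPH and glutathione enzymes 5 fell (mean -0.06) and of 310 zinc finger genes named Zfp 29 fell and 17 rose (mean -0.07), and both means were above 0 (0.02 and 0.01) with library totals as the only scaling and after removal of the length and GC trends (0.01 and 0.04). The Zfp genes numbered 28 higher and 16 lower with library totals, 8 and 7 after that removal, and 2 and 2 without knockout replicate 1, and the NADPH and glutathione genes lower numbered 1 without knockout replicate 1 and 9 without knockout replicate 2.

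Of 22 collagen genes outside type IV 12 rose, with a mean log2 fold change of 1.75 (camera adjusted p = 3e-12) and an adjusted p = 0.22 with an estimated correlation. The mean was 0.77 with 6 genes higher without knockout replicate 1, the library in which the mesenchyme genes were highest. Of 25 semaphorin and plexin genes, which guide axons and cell movement, 10 rose (mean 0.58), with Sema3f 2.42-fold and Plxnb1 1.53-fold higher. Of 16 Eph receptor and ephrin genes 5 rose (mean 0.75), with Ephb2 1.65-fold higher, and of 13 adhesion G protein-coupled receptor genes 5 rose (mean 0.80). Without knockout replicate 1 these 3 families had 2, 3 and 3 genes higher and means of 0.33, 0.43 and 0.45. Relative to the controls they were at 0.62, 0.85 and 0.87 in knockout replicate 1 and at 0.31, 0.41 and 0.40 in knockout replicate 2, the mesenchyme genes being at 2.30 and 0.39. After removal of the length and GC trends 5 collagen, 5 semaphorin and plexin, 3 Eph and ephrin and 4 adhesion receptor genes were higher, and 18, 14, 8 and 8 were without knockout replicate 2. Kinesins (6 higher and 3 lower of 33), tubulins (1 and 1 of 14) and solute carriers (13 and 15 of 177) went both ways.

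Mesenchyme and retina markers were highest in different knockout libraries. The retina list lay above the controls (-0.10 to 0.16) in both, at 0.60 and 1.42 in knockout replicates 1 and 2. The mesenchyme list did so only in knockout replicate 1, at 2.30 and 0.39 against -0.47 to 0.57 in the controls. The mean log2 ratio of knockout replicate 1 over replicate 2 was 1.92 for the 21 mesenchyme genes and -0.82 for the 21 retina genes, a difference of 2.74, against at most 1.08 between control libraries, and all 13 muscle genes were higher in knockout replicate 1. Of the mesenchyme genes 20 were higher in knockout replicate 1 and of the retina genes 20 in knockout replicate 2 (Fisher exact p = 1.6e-09), but this p treats genes that vary together as independent and compares 1 library with 1 library, so it decides nothing. The muscle list was at 2.96 and -0.33 in knockout replicates 1 and 2, against -0.57 to 0.78 in the controls. For muscle and mesenchyme genes, a response of lens cells to the loss of N-myc would have to differ between the 2 knockout libraries. Unequal amounts of tissue from outside the lens, from dissection or from a difference in the eyes, and such a response both stay open.

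The fall of cytosolic ribosomal protein genes had a mean log2 fold change of -0.50. It was -0.44 with the length and GC trends of the libraries removed (camera adjusted p = 1.1e-17), so the trends as fitted did not account for the whole fall. They were fitted on each symbol's longest transcript (median length 1100 for ribosomal protein genes), which may not be the one expressed. A length or GC bias is therefore not excluded. The list's call itself rests on the preset correlation, with an adjusted p = 0.44 with an estimated correlation. If outside tissue diluted the lens RNA, genes restricted to the lens would fall at least as far, and the abundant crystallin genes Cryaa and Crybb1 had log2 fold changes of 0.04 and 0.08. Of 38 crystallin and fibre genes 12 (31.6%) lay above the ribosomal protein mean by more than 2 SE, but several of these, such as Ank2, Cdh2 and Sptbn1, are also expressed outside the lens, so this share decides nothing and dilution stays open as a part of the fall.

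Mt1 was near 0 in the controls and at 94.8 and 97.3 CPM in the knockout libraries (ratio 0.975). Its neighbour Mt2, which is usually induced with it, had a log2 fold change of 0.79 (SE 0.74, adjusted p = 0.48) on counts of 1, 5 and 6 in the controls and 8 and 7 in the knockouts. The upper limit of 2.28 is below the 8.14 of Mt1, so a rise of Mt2 as large as that of Mt1 was excluded, and a smaller shared response stays open at these counts. Some transgenes carry metallothionein sequence, and counts from the Cre transgene would be equal in both knockout libraries and near 0 in the controls (highest count 6), as measured, but Cre and knockout go together here, so this was left open. Within 2 Mb of Mt1, with Mt1 and Nlrc5 left out because their calls had been seen, 17.6% of 34 genes differed between the groups against 16.6% elsewhere (Fisher exact p = 0.82). This left open a chromosome region that differs between the groups, Nlrc5 starting 255 kb from Mt1.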
